A study of Mus musculus with 4 samples.

How the data were processed

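RNA of 2 mouse cell lines was measured on 4 microarrays of 1 design, the Arraystar long noncoding RNA and mRNA array for mouse. C3H10T1/2 is a fibroblast-like line of mesenchymal progenitors and 3T3-L1 is a line of preadipocytes. Each line was sampled before induction of adipocyte differentiation (day 0) and at day 4, with 1 array per group. Per the labels' protocols, ribosomal RNA was removed from total RNA, and the remaining RNA was amplified along whole transcripts from both oligo(dT) and random primers and labelled with 1 dye, Cy3. All 4 arrays were on 1 slide and in 1 scan, per the file headers, so neither could be fitted as a batch.

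Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 11.0.1.1, and hold an intensity per spot that was background-subtracted and detrended within its array, with no scaling between arrays. They also hold the unprocessed spot and background medians and flags for spots well above background, saturated or not uniform. A separate deposited table holds the authors' processed values on the log2 scale. Its method was not given in the sources used here. Each of its columns followed the log2 scanner intensity of its own array (Pearson's r from 0.9994 to 1.000 over 60819 probes present in both) in the same direction and without centring. The column medians were 5.94, 5.93, 5.93 and 5.93 for C3H10T1/2 at days 0 and 4 and 3T3-L1 at days 0 and 4. Day 4 changes from that table and from quantile-normalized scanner values had r = 1.000 in each line. The table was used only as an alternative.

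The main values were log2 of the processed intensity minus the 75th percentile of the same array, over noncontrol probes without the negative control probes. Control spots and 15 probes that were printed once and were not uniform on an array were left out, and spots of repeated probes were averaged without the 112 spots marked as outliers. This left 60900 probes. A change was counted in a line where the probe was well above background on at least 1 of the 2 arrays and differed at least 2-fold. Where it was above background on 1 array only, the dim array was set to the higher of its own signal and the lowest signal above background on that array, and the fold was counted as a bound. With 1 array per group, a change within a line has no replicate check and no p-value was given for it.

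Over both lines, limma 3.58.1 (lmFit and eBayes, R 4.3.3) was fitted to probes above background on at least 2 of 4 arrays, with terms for cell line and day. The cell line is a block because both days of a line come from the same line. The residual has 1 degree of freedom per probe and holds the difference between the lines' responses, so a small p-value favours a like change in both lines. It does not measure the spread between repeated cultures. P-values were adjusted by the Benjamini-Hochberg method over the probes tested, with a threshold of 0.05. In simulated data of the same 38333 probes, with 200 changed probes, limma called 0% of probes changed 2-fold, 0% of those changed 4-fold and 53.5% of those changed 8-fold. With 2000 probes changed at each of these sizes at once, it called 13.5%, 88.2% and 98.5% of them, with 232 false calls.

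The scanner files name probes by the array maker's identifiers and pair them with no gene, apart from 15 probes with a RefSeq mRNA accession, each printed in 20 spots per array. All 15 matched a gene in the RefSeq table of the mouse assembly GRCm38. The array design used an older build, so no coordinates are given. Control probes named for Gapdh and Pgk1 with a species and a 3 or a 5, taken here as ends of the transcript (12 probes with 10 spots each), were read as well. Of 28 gene lists fixed before the data were examined, 27 held no gene that could be named, among them the adipocyte, lipid and cell cycle lists and the markers of other cell types; only the list of reference genes, with 8 of its 18 members, was scored. The rule fixed beforehand named up to 4 members per list and, without gene names, the 2 highest and 2 lowest probes of each comparison. Probe identifiers are printed for the changes shared by both lines only, and all 15 genes with a name are described, some of them outside the rule and chosen after their values were seen. A list's median was set among 10000 random lists matched on mean signal. The error of a single gene is the SD over its repeated spots on the same arrays, which is technical only.

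The alternatives were quantile normalization, the 75th percentile of the probes above background on all arrays, normexp background correction with an offset of 50 followed by quantile normalization, the authors' log2 values, a filter on all arrays, no filter, thresholds of 1.5-fold and 4-fold, a fit without the cell line, and an intensity trend in eBayes. The normexp alternative used the median spot and background intensities of the deposited files in place of the mean. Figures were drawn with matplotlib 3.10.9.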

Results

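The series title and design text name the aim as finding long noncoding RNAs and mRNAs that change during adipocyte formation. Signals were above background for 59.0% of the 60900 probes in C3H10T1/2 at day 0 and 60.1% at day 4, and for 63.9% and 60.6% in 3T3-L1. Of 300 spots with negative control probes, 5, 5, 3 and 6 were called above background on these arrays. No spot was saturated. The 75th percentile of the intensity was 321 and 364 in C3H10T1/2 and 388 and 356 in 3T3-L1 at days 0 and 4. There were no replicate arrays, and the number of arrays limits the precision of every value.

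The first comparison asked which transcripts differed between day 4 and day 0. Among the 15 genes with a name, the transferrin receptor Tfrc, which takes up iron, had the largest difference in C3H10T1/2. Its signal was 8.52-fold higher at day 4 in C3H10T1/2 (log2 change 3.09 ± 0.08, SD over 20 spots) and 1.96-fold higher in 3T3-L1 (0.97 ± 0.09). G6pd2, a copy of the gene for the enzyme that starts the pentose phosphate pathway, was higher by nearly equal amounts, 2.74-fold in C3H10T1/2 (1.45 ± 0.08) and 2.64-fold in 3T3-L1 (1.40 ± 0.10). G6pd2 is a near-identical copy of the X-linked G6pdx, so which of the genes gave this signal is uncertain. Over both lines neither passed limma, with a mean log2 change of 2.03 ± 0.55 (SE, adjusted p = 0.136) for Tfrc and 1.43 ± 0.29 (adjusted p = 0.0743) for G6pd2. They were the 2 of the 15 genes with an unadjusted limma p under 0.05, 0.0130 for Tfrc and 0.00371 for G6pd2. Without a filter on dim probes both passed (limma adjusted p = 0.000886 and 0.0466), and G6pd2 passed with the filter on all arrays (limma adjusted p = 0.0371). The fit without a filter took in all 60900 probes, and its smallest limma adjusted p was 3.1e-92, against 0.00525 in the main fit. Tfrc passed there although its changes in the lines were 3.09 and 0.97, so that p-value does not mean that both lines changed alike. Over all alternatives the limma adjusted p ran from 0.000886 to 0.299 for Tfrc and from 0.0371 to 0.186 for G6pd2.

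The RefSeq probe of Gapdh, an enzyme of glycolysis, was 1.37-fold higher in C3H10T1/2 (0.45 ± 0.05) and 1.63-fold higher in 3T3-L1 (0.70 ± 0.08), with a limma adjusted p of 0.380 over both lines. The 6 control probes named for Gapdh were higher by 1.09 to 2.04 on the log2 scale in C3H10T1/2 and by 1.32 to 2.47 in 3T3-L1. Control probes named for Pgk1, which makes ATP later in the same pathway, were higher by 1.38 to 2.69 in C3H10T1/2 and by 1.22 to 2.45 in 3T3-L1. All 12 control probes stayed above 0 under the other scalings run on them. Probes of one gene disagreed by more than their spot SD, and the dimmer probes gave the larger changes. The mouse 3' probe of Pgk1 went from 40421 to 119190 intensity units in C3H10T1/2 (2.60-fold), while the mouse 5' probe went from 216 to 1261 (5.16-fold). Gapdh has many processed pseudogenes, and which transcripts each probe reads was not tested.

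**Figure D1:**
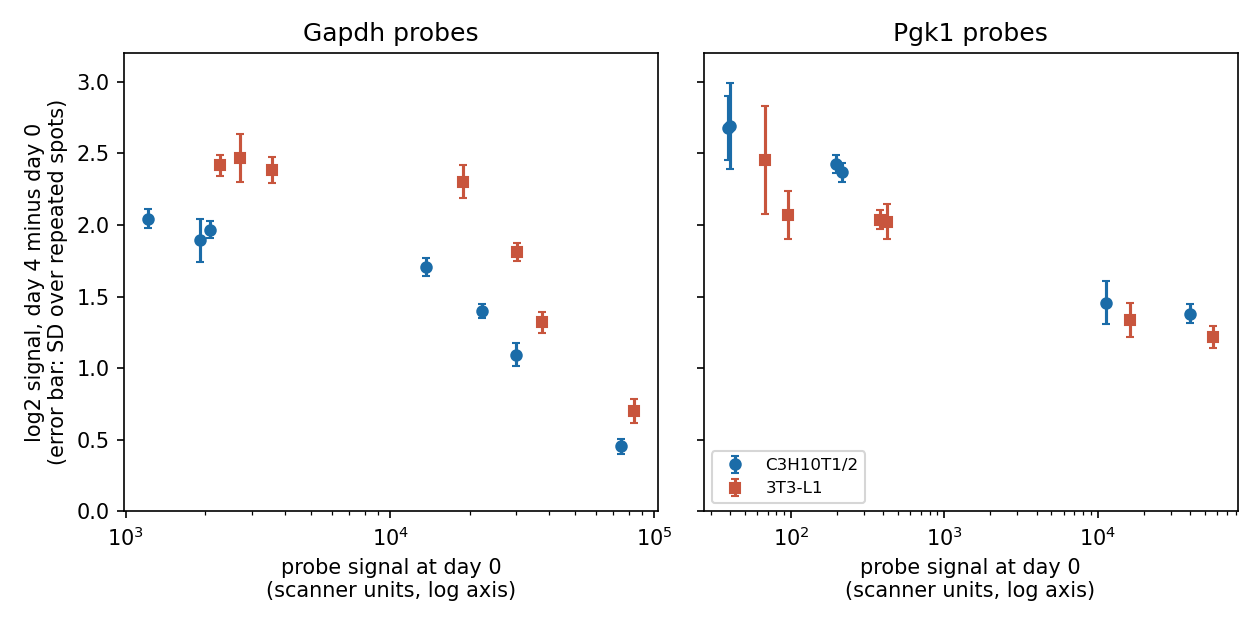
Change in log2 signal from day 0 to day 4 against the day 0 signal (scanner units, log axis) for 7 probes of Gapdh and 6 of Pgk1, in C3H10T1/2 (circles) and 3T3-L1 (squares), with bars giving the SD over repeated spots. The brightest Gapdh probe changed by 0.45 and 0.70, and the largest Gapdh changes were 2.04 and 2.47.

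The list of reference genes, fixed before the data were examined, had 8 members with a name. Its median log2 change was -0.20 in C3H10T1/2 (mean -0.06, the 17.8th percentile of matched random lists) and 0.17 in 3T3-L1 (mean 0.11, the 65.7th percentile). The median in 3T3-L1 turned below 0 under quantile normalization (-0.04), normexp (-0.03) and the authors' values (-0.01). None of the 8 passed limma over all probes, 0 passed adjusted over the list alone, and 0 had an unadjusted limma p under 0.05. Hprt, an enzyme of purine salvage, was 2.22-fold higher at day 4 in 3T3-L1 (1.15 ± 0.09) and 1.31-fold higher in C3H10T1/2 (0.39 ± 0.12), with a limma adjusted p of 0.310. B2m, the light chain of class I histocompatibility molecules, had lower signals at day 4 in both lines, with log2 changes of -0.35 ± 0.07 and -0.81 ± 0.06 (limma adjusted p = 0.394). Gusb, a lysosomal enzyme, was 1.86-fold lower in 3T3-L1 (-0.89 ± 0.04), against -0.08 ± 0.06 in C3H10T1/2 (limma adjusted p = 0.533). Log2 changes of Tbp, a general transcription factor, were -0.33 ± 0.06 in C3H10T1/2 and 0.24 ± 0.11 in 3T3-L1. For Actb, a cytoskeletal actin, they were -0.32 ± 0.06 and 0.13 ± 0.07, and for the peptidyl-prolyl isomerase gene Ppia -0.36 ± 0.04 and 0.15 ± 0.05. The ribosomal protein gene Rpl13a had 0.10 ± 0.05 and 0.18 ± 0.08. Actb and Ppia have many processed pseudogenes, and which transcripts their probes read was not tested. The values of Actb and Ppia in 3T3-L1 and of Rpl13a in both lines turned below 0 in 3 of the 4 other normalizations.

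Outside that list, the chaperone gene Hsp90ab1 had log2 changes of -0.12 ± 0.08 in C3H10T1/2 and 0.59 ± 0.08 in 3T3-L1, and glycerol kinase, Gk, had -0.20 ± 0.17 and 0.50 ± 0.13. Nono, which encodes an RNA-binding protein of paraspeckles, was 1.70-fold lower in C3H10T1/2 (-0.76 ± 0.04) and 1.13-fold higher in 3T3-L1 (0.18 ± 0.05). Under the 4 other normalizations the 3T3-L1 value ran from 0.02 to 0.10. Tuba1b, an alpha-tubulin gene with near-identical copies, had -0.12 ± 0.06 and 0.07 ± 0.08, of which the second turned below 0 in all 4 other normalizations and the first above 0 in 2. Ldhal6b was near background, with 1, 19, 20 and 6 of 20 spots above it on the 4 arrays. By the bounds of the main values, it was 1.47-fold higher at day 4 in C3H10T1/2 and 2.27-fold lower in 3T3-L1. Without bounds, its log2 changes under the 4 other normalizations ran from 0.23 to 0.78 in C3H10T1/2 and from -1.26 to -0.37 in 3T3-L1. None of these 5 genes passed limma over both lines (adjusted p from 0.753 to 0.982).

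**Figure D2:**
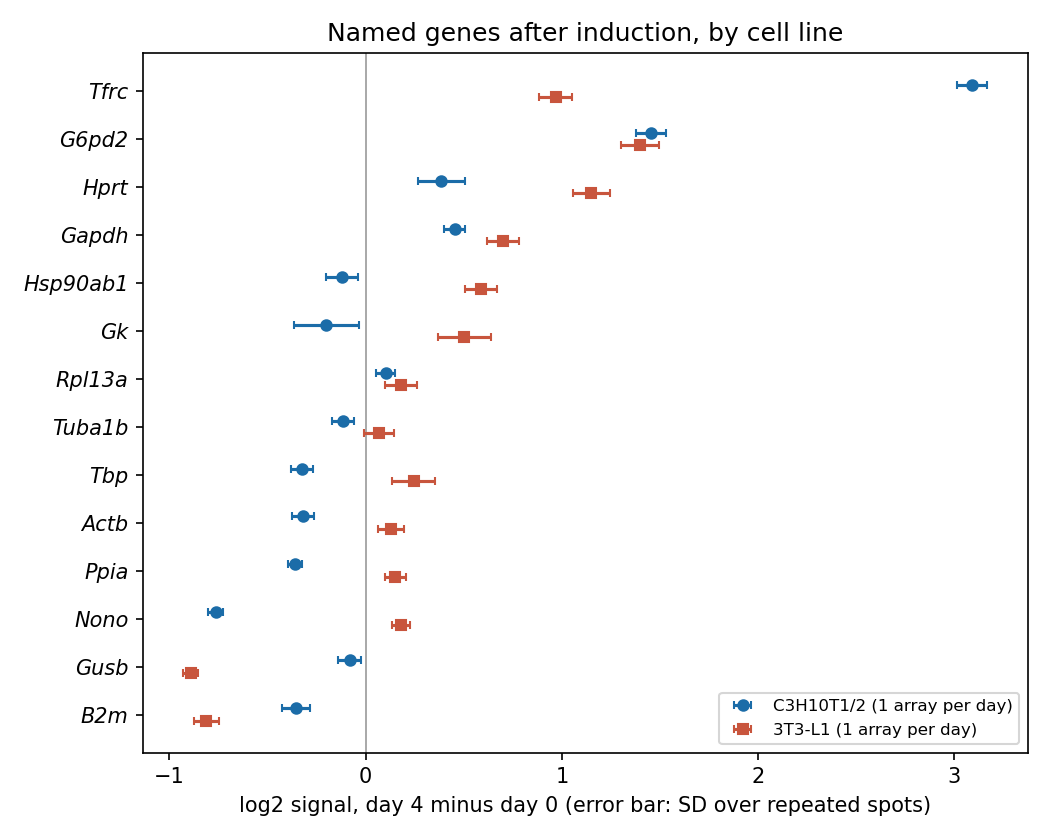
Change in log2 signal from day 0 to day 4 for 14 named genes in C3H10T1/2 (circles) and 3T3-L1 (squares), 1 array per group, with bars giving the SD over 20 spots. Tfrc lies at 3.09 and 0.97, G6pd2 at 1.45 and 1.40, and Gusb and B2m have the lowest values in 3T3-L1, -0.89 and -0.81.

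Across all probes, 3262 were at least 2-fold higher and 2919 at least 2-fold lower at day 4 in C3H10T1/2, of 38303 above background on at least 1 of its arrays. In 3T3-L1 3399 were higher and 4273 lower, of 40237. Of these, 663 higher and 655 lower probes in C3H10T1/2, and 450 and 1045 in 3T3-L1, were counted by their bounds. Changes of at least 16-fold were counted for 180 higher and 44 lower probes in C3H10T1/2 and for 122 and 94 in 3T3-L1. Repeated spots of the named genes, most of which were bright, had a median SD of 0.08 in their log2 change, a technical error within these arrays that gives no spread between cultures.

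Many probes changed in the same direction in both lines. Of 36949 probes above background in each line, 1551 were at least 2-fold higher in both, against 261 for independent lists, and 1321 were lower in both, against 270. Opposite changes were fewer than independent lists would give. A total of 137 probes were higher in C3H10T1/2 and lower in 3T3-L1 (independent lists 314), and 49 went the other way (224). The lines share no array, so no common control adds to this overlap. Changes in the lines had Pearson's r = 0.56 and Spearman's rho = 0.45 across 38333 probes, which are not independent replicates.

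**Figure D3:**
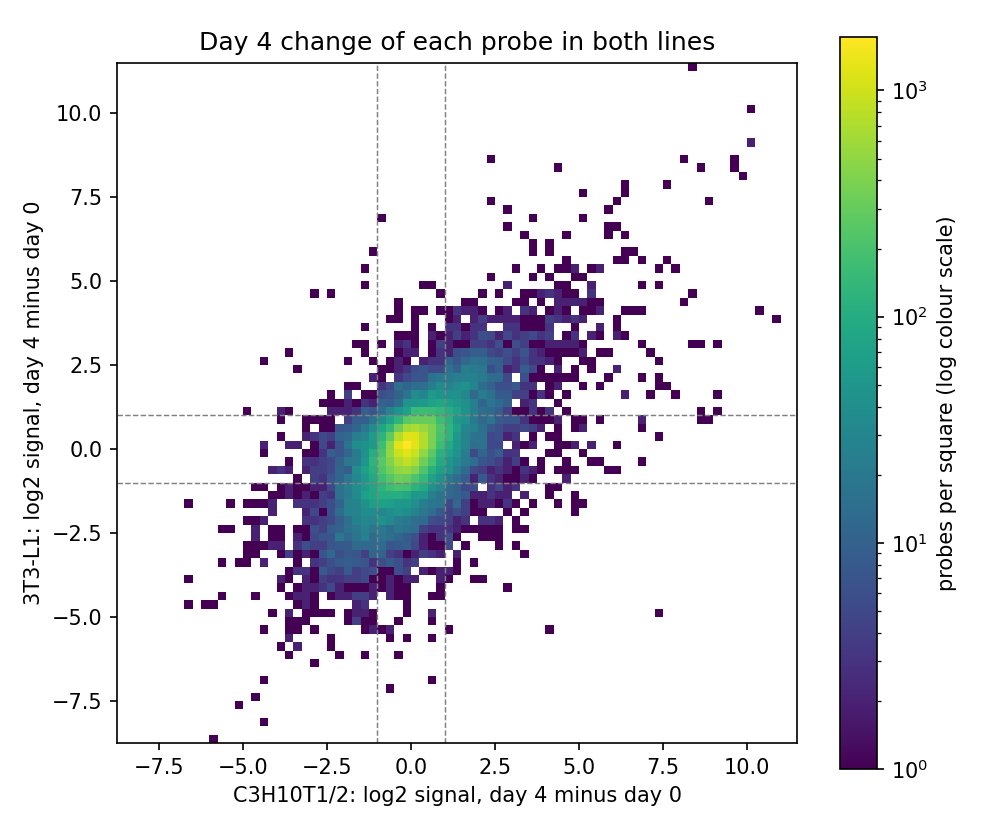
Number of probes (colour, log scale) by their change in log2 signal from day 0 to day 4 in C3H10T1/2 (horizontal axis) and 3T3-L1 (vertical axis), in squares of 0.25, over 38333 probes above background on at least 2 arrays, with dashed lines at 2-fold. The cloud runs from lower left to upper right, with r = 0.56.

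Over both lines, limma called 666 probes that rose and 460 that fell at adjusted p under 0.05, of 38333 tested. Taken without the bounds for dim arrays, all 1126 had changed at least 2-fold the same way in each line. The call itself favours such agreement, because the residual holds the difference between the lines' responses. The smallest mean log2 change among them was 1.75 in size. The files pair these probes with no gene. Among the 676 called probes above background on all arrays, the highest by the smaller of the changes were ASMM10P054528 and ASMM10P018642. The signal of ASMM10P018642 rose 285-fold in C3H10T1/2 and 414-fold in 3T3-L1 (mean log2 change 8.42 ± 0.31, SE, limma adjusted p = 0.00525), and that of ASMM10P054528 rose 970-fold and 287-fold (9.04 ± 0.48, limma adjusted p = 0.0109). The most lowered were ASMM10P052682, 17.5-fold and 30.4-fold (-4.53 ± 0.33, limma adjusted p = 0.0166), and ASMM10P024123, 15.7-fold and 60.8-fold (-4.95 ± 0.52, limma adjusted p = 0.0254). Their day 4 levels were -2.39 and -2.91 for ASMM10P052682 and 2.58 and -1.98 for ASMM10P024123. Day 0 levels of the raised probes were -1.11 and -3.18 for ASMM10P018642 and -2.64 and -1.48 for ASMM10P054528 (C3H10T1/2 and 3T3-L1). The large rises rest on these dim day 0 signals, so their sizes are uncertain. With normexp on median signals followed by quantile normalization 67 rose and 10 fell, and without the cell line term limma called 0 probes, with 4857 at an unadjusted p under 0.05.

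Among the tested probes, 399 were above background at day 4 and not at day 0 in both lines, of which 133 were at least 2-fold higher in each by their bounds. In the other direction 648 were above background at day 0 and not at day 4 in both, 153 of them at least 2-fold lower in each.

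The second comparison set 3T3-L1 against C3H10T1/2. At day 0, Tfrc was 2.37-fold higher in 3T3-L1 (log2 difference 1.25 ± 0.07, SD over 20 spots), and at day 4 it was lower there (-0.88). Actb (-0.67 ± 0.05), Hprt (-0.67 ± 0.08) and Ppia (-0.61 ± 0.07) had lower signals in 3T3-L1 at day 0. Over all probes, 3050 were at least 2-fold higher and 2544 lower in 3T3-L1 at day 0, and 2581 and 3231 at day 4. Over both days, limma called 654 probes higher in 3T3-L1 and 497 higher in C3H10T1/2, and none of the 15 named genes (adjusted p from 0.615 to 0.997, with 0 at an unadjusted p under 0.05). A total of 1014 probes were above background on both 3T3-L1 arrays and neither C3H10T1/2 array, and 370 the other way. These are detection calls with no fold threshold. The 3T3-L1 day 0 array had the most probes above background, 63.9%, against 59.0% in C3H10T1/2 at day 0. The days are the only replication of the line contrast. With normexp and quantile normalization, limma called 157 and 113.

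The third comparison concerned the difference between the responses, which has no test in this design. Tfrc had the largest difference among named genes above background on all arrays, with a 3T3-L1 response minus C3H10T1/2 response of -2.12 ± 0.11 on the log2 scale (SD over spots). For G6pd2 the difference was -0.05 ± 0.13. Among 38333 probes, taken without bounds for dim arrays, the 3T3-L1 response was higher by at least 1 on the log2 scale for 2828 and lower for 4164. Among the 32829 above background on all arrays, these counts were 2151 and 2823.

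Some probes carry names that mark them as long intergenic noncoding RNAs. At day 0 in C3H10T1/2, 22.4% of 1102 probes named for human lincRNAs, 24.3% of 649 named for mouse lincRNAs and 33.7% of 83 named MM9LINCRNAEXON were above background, against 60.4% of the 58128 probes of the main ASMM10P series. In C3H10T1/2 8 human-named probes were at least 2-fold higher and 10 lower at day 4, of 286 above background on at least 1 array. In 3T3-L1 the counts were 16 and 15 of 323. The mouse-named probes gave 3 and 7 of 177 in C3H10T1/2 and 16 and 7 of 202 in 3T3-L1. The MM9LINCRNAEXON probes gave 1 and 4 of 33, and 2 and 3 of 33. Of the ASMM10UP series, whose meaning the files do not give, 8 probes were higher and 36 lower in C3H10T1/2, of 352. In 3T3-L1 12 were higher and 66 lower, of 401. In the ASMM10P series 8.65% were higher and 7.64% lower in C3H10T1/2, and 8.53% and 10.6% in 3T3-L1. Limma called 1 of 177 tested mouse-named probes, which rose, and 1 of 285 human-named and 1 of 33 MM9LINCRNAEXON probes, which fell. In the ASMM10UP series 1 rose and 6 fell, of 355, against 664 and 452 of 37468 in the ASMM10P series.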

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

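The tests of explanations weighed here were chosen after the results were seen.

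In the main values, signals of Nono and Ppia differed from day 0 in opposite directions in the lines at every spot. This difference was not tested because there was 1 array per group. The 3T3-L1 response minus the C3H10T1/2 response was 0.944 on the log2 scale for Nono and 0.509 for Ppia. The change of Nono in 3T3-L1 shrank to 0.10 with the other 75th percentile, 0.04 under quantile normalization, 0.03 with normexp and 0.02 with the authors' values. The last 3 are below its spot SD of 0.05, so under these Nono was lower in C3H10T1/2 with little change in 3T3-L1. Under the 4 other normalizations the difference between the responses stayed between 0.90 and 0.94 for Nono. For Ppia it was all but lost in 3 of them, with 0.02 under quantile normalization, 0.07 with normexp and 0.10 with the authors' values, where both lines had values below 0. Whether the Ppia probe also reads pseudogene copies was not tested.

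A control probe outside the main measurement, (+)E1A_r60_a20, was above background on the 3T3-L1 arrays, with signals of 121 and 57.7 at days 0 and 4, but not in C3H10T1/2, with 6.63 and 6.88. The log2 difference of 3.51 as the mean of both days is therefore set by the floor of the C3H10T1/2 arrays, and against their lowest signal above background the probe was at least 4.09-fold brighter at day 0 and at least 2.35-fold at day 4. A spike-in mix added to the 3T3-L1 samples would have raised the other 9 E1A probes, whose highest difference was 0.20, and a fault of 1 array is argued against by 35 of 35 spots above background on both 3T3-L1 arrays. Of the 6 control probes named DCP_20, 3 were at least 2-fold brighter in 3T3-L1 on both days by the same bound. Of these, DCP_20_0 had signals of 138 and 58.0 in 3T3-L1 at days 0 and 4, close to those of (+)E1A_r60_a20. Whether the DCP_20 probes share its sequence was not tested, so they are not separate evidence. A matching transcript of the 3T3-L1 cells, which may be present, and a source in the handling of that line's samples cannot be told apart, because line and handling coincide in these 4 samples.

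The control probe ETG10_13482 had the opposite difference, with a log2 value of -2.45, from signals of 49.7 and 47.7 in C3H10T1/2 and 10.5 and 8.99 in 3T3-L1. Only 1 of its 12 spots was above background on each 3T3-L1 array, so the difference is bounded, at 2.41-fold or more at day 0 and 2.00-fold or more at day 4.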

How the results depend on the processing

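The alternatives here were fixed before the data were examined. Of 108 values of the counts, correlations and list medians, 66 stayed within 1.5 times of their main value or within their spread (within 0.1 for r), among them all those under quantile normalization, the other 75th percentile, the authors' values and an intensity trend in eBayes. Quantile normalization called 1360 probes for day, which included 1115 of the 1126. For the other values the cause was not tested, except where another threshold or filter changes the count by its construction. With normexp on median signals, an offset and quantile normalization together, 2066 probes were higher and 1584 lower in C3H10T1/2, 1972 and 2373 in 3T3-L1, 992 and 701 in both lines, and 1916 and 1494 between lines at day 0. Limma then called 67 and 10 for day and 157 and 113 for line, and all 77 of the former were among the 1126. Without a filter 4601 probes were lower in C3H10T1/2, 4831 were higher and 3927 lower between lines at day 0, limma called 2000 and 2098 for day and 1748 and 1688 for line, and r between the responses was 0.448. With the filter on all arrays limma called 1016 and 733 for day, of which 676 were among the 1126, and 370 and 304 for line. Without the replicate block, here the cell line that pairs the days, limma called 0 and 0, with 4857 at an unadjusted p under 0.05. At 1.5-fold the counts were 6311 and 6562 in C3H10T1/2, 7559 and 8159 in 3T3-L1, 3187 and 3081 in both, and 6158 and 6211 between lines at day 0. At 4-fold they were 976 and 571, 881 and 1091, 392 and 207, and 991 and 718. The share of higher probes in C3H10T1/2 was 52.8%, 46.7% with the other 75th percentile and 63.1% at 4-fold. There were 357 values of single genes, probe families and shares of higher probes. Of these, 240 stayed within a margin or on their side of the threshold, 114 moved further, and 3 passed the threshold anew (Tfrc and G6pd2, given above). The margin was the spot SD for a gene's change in a line and the limma SE where a line was left out. For families it was 0.1 on the log2 scale and for shares 10 percentage points. Actb, Ppia, Rpl13a and Tuba1b changed sign in at least 1 line under another normalization. Without each line in turn, the remaining line's change has no test. For Tfrc it was 0.97 and 3.09, for G6pd2 1.40 and 1.45, and for Nono 0.18 and -0.76. A count per named gene, a mean over a gene's probes and a slide block were not run, because 15 genes had 1 probe each in the main set and there was 1 slide. Dim probes are limited by their signal over background, since 19309 of 60900 probes were above it on no array.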

Other observations

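The probe families, relations and tests of explanations in this part were chosen after the data were seen, and the normalizations applied to them had been set before.

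In the ASMM10UP series, the median log2 change in 3T3-L1 was -0.06, against 0.06 for matched probes (0.12th percentile), and in C3H10T1/2 -0.08 against -0.06 (32.0th percentile).

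The changes of Gapdh and Pgk1 probes fell with the probe's day 0 signal. Over 7 Gapdh probes Spearman's rho was -0.96 in both lines (exact permutation p = 0.00278, two-sided, adjusted 0.00370 over 4 relations), with Pearson's r of -0.92 and -0.88 (exact permutation p = 0.000397 and 0.00278). Over 6 Pgk1 probes rho was -0.94 in C3H10T1/2 (exact permutation p = 0.0167, adjusted 0.0167) and -1 in 3T3-L1 (0.00278, adjusted 0.00370), with r of -0.99 and -0.97 (exact permutation p = 0.00278 and 0.00139). Without the 2 probes farthest from the median signal, r was -0.91 and -0.86 for Gapdh and -0.99 and -0.75 for Pgk1. The probes read the same genes on the same arrays, so they are not independent samples.

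A position effect along the transcript would raise every probe named 5' over its 3' partner. The mouse-named and human-named pairs went that way in both lines, with 5' minus 3' differences from 0.61 to 1.22, but their 5' probes were also the dimmer ones. The rat-named Gapdh pairs lay within 2 SE of 0, with 0.08 ± 0.05 and -0.087 ± 0.061 (SE over 10 spots, C3H10T1/2 and 3T3-L1). The rat-named Pgk1 pairs went the other way, with -0.26 ± 0.10 and -0.42 ± 0.12. Position stays open, also because all rat-named and human-named Pgk1 pairs held a probe near the floor, which in the rat-named pairs was the 3' probe. Another candidate explanation, compression of the signal of bright probes, predicts the same trend in another contrast, and the day 0 difference between lines fell with brightness for Gapdh (rho = -0.96, exact permutation p = 0.00278, adjusted 0.00556) but gave rho = -0.66 for Pgk1 (exact permutation p = 0.175, adjusted 0.175), which leaves it open. Cross-hybridization of the rat-named and human-named probes was not tested, and no biological explanation was tested.

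In 3T3-L1 the lincRNA-named probes lay above other probes of their signal level. The median log2 change of 257 human-named probes was 0.30, against 0.06 for matched probes (100th percentile of 10000 random lists), that of 161 mouse-named probes was 0.18 (98.7th percentile), and that of 29 MM9LINCRNAEXON probes was 0.31 (96.3rd percentile). In C3H10T1/2 the medians were -0.10, -0.11 and -0.10 (28.8th, 23.9th and 35.3rd percentiles). Negative control probes moved alike on the scaled values, by 0.23 ± 0.16 (SD over 15 probes) in 3T3-L1 and -0.10 ± 0.15 in C3H10T1/2. Before scaling, their signal at days 0 and 4 was 6.69 and 7.20 in 3T3-L1 and 7.23 and 7.61 in C3H10T1/2. This signal rose in both lines, so the opposite signs of the negative control probes come from the scaling of the arrays. The distance from matched probes shrank with normexp in all 3 families, from 0.23 to 0.11 for the human-named probes. It went from 0.12 to 0.08 for the mouse-named and from 0.23 to 0.08 for the MM9LINCRNAEXON probes. The normexp setting adds an offset to every signal, which shrinks log2 changes of dim probes whatever their cause. The smaller distances therefore cannot tell a background signal from another cause. An additive background should not reach bright probes. However, 133 probes of these 3 families with higher signal still lay 0.17 ± 0.05 above matched ones in 3T3-L1 (99.8th percentile). In C3H10T1/2 the distance was -0.08 ± 0.04 (6.03rd percentile). The errors are bootstrap SEs of the family median alone. The matched median was held fixed and probes were drawn as if independent, so the error of the distance may be larger. Signal of low specificity in proportion to total RNA and a rise of these transcripts in 3T3-L1, as a hypothesis, both stay open, and the difference between the lines was not tested.

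Most lincRNA-named probes come in pairs whose names differ in a plus or a minus sign. Both members of 71 of 874 pairs were above background on at least 2 arrays, against 62.1 for independent members (Fisher's exact test, p = 0.141). Across those 71 pairs the day 4 changes of the members had rho = -0.09 in each line.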
